A study of Mus musculus with 6 samples.

How the data were processed

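The 6 samples are pancreatic tumours of KPC mice, 3 after IPI-926 at 40 mg/kg daily by oral gavage and 3 after vehicle, each collected 2 hours after the last dose and made into 1 single-cell library. The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization, for 32285 genes. Per the file headers they were made with cellranger 6.1.2, while the submitters' processing notes name Cell Ranger 2.1.1 and the mm10 genome, and the annotation is not stated. Of the gene identifiers 32158 are in GENCODE vM21 on GRCm38, from which positions were taken, and 127 are not. Across the libraries 62905 barcodes carried 718531446 UMIs. No library duplicated another: the smallest chi-square per degree of freedom between the profiles of any pair was 286.8, and the most barcodes any pair shared was 59.

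Cells with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were kept, 54911 in all. Doublets were scored in each library by the share of simulated doublets among the 20 nearest neighbours of a cell, in 30 principal components of 2000 variable genes, with 2 simulated doublets per cell made from different coarse clusters and at least 25% of the UMIs from the smaller parent. The top 0.8% per 1000 barcodes were removed, 5114 cells, which left 49797. This score is a revision. The first score paired cells at random and the second paired cells of different clusters, both with more neighbours, and both mostly marked rare stromal cells with many UMIs. The last changes were made after cluster and library values of Gli1, Ptch1, Wif1 and Axin2 had been seen. They were judged on which cell types were marked. The score decides which IPI-926 libraries reach 20 cells in a class. Fibroblasts of IPI-926 replicate 2 did not with the second score (0.26% of kept cells, against 1.13% with the final score). Perivascular cells of IPI-926 replicate 3 did with the first score (0.28%, against 0.13% with the final score). Those of IPI-926 replicate 1 did not with the second score (0.20%, against 0.38% with the final score). Both earlier scores were run as alternatives, as were results with doublets kept.

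Counts scaled to 10000 per cell and log transformed were clustered over all libraries together with Leiden at resolution 1, without batch integration and without sex-linked genes. A cluster took the class whose markers led it when at least 3 of them were detected, at 50 CPM or more, in at least 25% of its cells and at more than 2-fold the other cells (pseudocount 5 CPM), unless another class had more markers among its top 10 genes, or its UMIs were below the library median divided by 3 with no marker among the top 10 genes. Of 36 clusters 8 stayed unnamed, with 7744 cells, and 42053 cells were named. Fibroblasts and endothelial cells were clustered again without the genes of the Hedgehog target and WNT antagonist lists.

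Raw counts were summed per library and class, and a library entered a class with at least 20 cells. Classes with at least 2 libraries per group were tested with edgeR 4.0.16 (TMM scaling, filterByExpr by group, robust quasi-likelihood test), with Benjamini-Hochberg adjustment over the genes tested in the class and a threshold of 0.05. Acinar and plasma cells had too few libraries. Scaled CPM are edgeR's CPM of these sums after TMM scaling, log2 fold changes are IPI-926 minus vehicle, and the SE of a fold is its size over the root of the F statistic. Gene lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, two-sided and adjusted over the lists of a class, with fry and camera with an estimated correlation as alternatives. None of the camera calls in any class held with an estimated correlation. Single genes of a list were also adjusted over the list alone. The markers of every other class were tested in each class beside the 39 fixed lists.

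Shares of cells were compared by a two-sided exact permutation test over the 20 assignments of the libraries, which cannot go below p = 0.1. The difference of response between fibroblasts and another class was tested with limma (trend, robust) on the difference of log2 CPM (prior count 2) between the classes within a library. The labels give no pairing, so none was used. Groups, tests, thresholds, gene lists, class markers, the rule for named genes and most alternatives were set before the data were examined, while the details of the detection of markers and the doublet revision were set after.

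The rule named, in each main class, every Hedgehog target in fibroblasts and perivascular cells, the members of WNT and VEGF related lists that pass, and Gli1, Ptch1, Hhip, Wif1, Axin2, Lef1, Vegfa, Kdr, Esm1, Shh and Ihh whatever their result. It added the 10 rising and 10 falling genes of largest change among those that pass with a mean of at least 10 CPM and groups that do not overlap, the 5 rising and 5 falling genes of smallest p where fewer than 10 pass, and 4 genes of any other list that passes. Sex-linked, predicted and other classes' marker genes were left out of the part on largest change. For smaller classes it took 3 rising and 3 falling genes. An item that the rule names is not reported here.

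The alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, no expression filter, a mean of at least 10 CPM, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial), doublets kept, Leiden resolutions 0.5 and 2, equal cells per library, means of per-cell CPM, genes without sex-linked and other classes' markers, a threshold of 0.1, other denominators and tests for shares, other sub-clusterings, and leaving out each library. Added after seeing the data were the earlier doublet scores, fibroblasts and iCAF-like cells without the cluster of IPI-926 replicate 3, and unnamed clusters joined to the class with the most markers.

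The tests were tested on simulated data built on the same libraries, with 200 changed genes. In fibroblasts edgeR recovered 4.48% of genes changed by a log2 fold of 1, 22.4% at 2 and 80.3% at 4, with 9 false calls, and in endothelial cells 14.9%, 91% and 93.9% with 13. In perivascular cells recovery was 2.99%, 52.2% and 89.4%, in ductal cells 2.99%, 44.8% and 86.4%, in macrophages and monocytes 5.97%, 44.8% and 89.4%, and for all cells summed 0%, 2.99% and 45.5%. A list of 10 genes shifted by a log2 fold of -1 was called by camera in 6 of 6 tests, by camera with an estimated correlation in 0 and by fry in 2. Genes were drawn independently of each other and the lists were random. The simulation therefore cannot tell whether calls at the preset correlation hold for genes that vary together. Floors cover counting error only, and the interval of a correlation covers the resampling of genes only. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and statmod 1.5.0.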

Results

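Single-cell RNA was measured with 10x Genomics Single Cell 3' v3 libraries from pancreatic tumours of KPC mice, a genetically engineered model of pancreatic ductal adenocarcinoma. IPI-926, an inhibitor of the Hedgehog signal transducer Smoothened, was given to 3 mice and its vehicle to 3 others, and tumours were taken after 2 days of dosing. The comparison asks which cells and genes of the tumour differ after this brief block, with Hedgehog, WNT and VEGF signalling named in the study's design. The vehicle libraries (replicates 1 to 3) held 102399658, 106672146 and 132827800 UMIs, and the IPI-926 libraries 100810942, 100891572 and 174929328. After filtering, 6595, 8578 and 6916 vehicle cells and 7368, 6184 and 14156 IPI-926 cells remained. Vehicle cells were deeper, with a median of 6157.5 ± 1856 UMIs per cell (mean ± SD of 3 libraries) against 3252 ± 512 (two-sided exact permutation p = 0.1, the smallest that 3 libraries against 3 can give). Each group held 1 female mouse, by the expression of sex-linked genes.

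The tumours held epithelial, stromal and immune cells in proportions that differed between mice. Macrophages and monocytes were the most frequent named class with 12552 cells, followed by ductal epithelial cells with 8575, neutrophils with 7865, fibroblasts with 4227, T cells with 2930, mesothelial cells with 1680 and endothelial cells with 1616. B cells numbered 1035, dendritic cells 847, plasma cells 284, perivascular cells 263 and acinar cells 179. IPI-926 replicate 3 stood apart. It supplied 99.9% of a fibroblast cluster of 1885 cells led by Crabp1, Cthrc1, Thbs2 and Postn, and 99.8% of an unnamed cluster of 4550 cells. The first held a median of 44543 UMIs per cell, 11.66-fold that of its library, and the second 1246. Without the first of these clusters, named by 17 detected fibroblast markers, this library keeps 49 fibroblasts. Whether the cells of that cluster are fibroblasts or tumour cells of mesenchymal form was not tested. The library also supplied 2655 of 2845 and 1407 of 1421 cells of 2 macrophage clusters, out of its 4221 macrophages and monocytes, 963 of 976 cells of a T cell cluster and 535 of 586 of a ductal cluster. Fibroblast sums of the IPI-926 group therefore rest on 281, 70 and 1933 cells.

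Hedgehog target genes were lower in the fibroblasts of IPI-926 tumours. Gli1, the transcription factor induced by the pathway and its usual readout (ENSMUSG00000025407, GRCm38 chromosome 10 from 127329882 to 127341974), averaged 10.5 ± 1.79 scaled CPM in vehicle fibroblasts and 0.699 ± 0.803 after IPI-926 (SD, n = 3 each), a log2 fold change of -4.97 (SE 0.83). Ptch1, the Hedgehog receptor that the pathway itself induces (ENSMUSG00000021466, chromosome 13 from 63508328 to 63573598), was 24.95 ± 8.49 against 6.65 ± 3.11, a log2 fold change of -1.98 (SE 0.50). The secreted signal Bmp4 was 19.7 ± 8.12 against 3.98 ± 2.18, and the mesenchymal transcription factor Foxf2 6.01 ± 1.72 against 1.67 ± 1.08. These 4 members of the Hedgehog target list fell when adjusted over its 8 tested members alone (edgeR, adjusted p = 0.0046 for Gli1, 0.015 for Ptch1 and Bmp4 and 0.0416 for Foxf2). In each of the 4, every IPI-926 library lay below every vehicle library, which 1 of the 20 assignments of the libraries gives by chance.

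Over all 12144 genes tested in fibroblasts none passed (edgeR, adjusted p = 0.8995 for Gli1), with 438 genes at an unadjusted p under 0.05. That is fewer than the share of 0.05 of tested genes that no difference would give on average. The counts at this p given below, for other classes, all cells summed and differences between classes, were also under that share. DESeq2 called 36 genes in fibroblasts, Gli1 among them with an adjusted p = 7.815e-05, and limma-voom called 0. As a list, the Hedgehog targets had a median log2 fold change of -2.05, with 6 of 8 members negative (camera, adjusted p = 2.991e-08), and an adjusted p = 0.3774 with an estimated correlation. Foxf1, Osr1 and the WNT antagonist Sfrp1 did not fall over the list alone, at log2 fold changes of 0.62, 0.86 and -0.16 (adjusted p from 0.8909 for Sfrp1 to 0.2215 for Osr1 over the list alone). Wif1, a secreted WNT inhibitor, was too unevenly detected to be tested: it stood at 23.8, 1.84 and 58.2 scaled CPM in the vehicle libraries and at 0.305, 0 and 0.045 in the IPI-926 libraries, on 341 UMIs in all. Hhip with 112 UMIs, Foxl1 with 62 and Foxd1 with 16 were not tested either.

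Without the fibroblast cluster that IPI-926 replicate 3 supplies, Gli1 stood at a log2 fold change of -4.27 (SE 0.67), Ptch1 at -1.88 (SE 0.60) and Bmp4 at -1.55 (SE 0.49), and these 3 fell over the list alone, while Foxf2 turned to 0.33 (SE 0.95) and the median of the list to -0.61. With equal cells per library only 4 members could be tested, and their median was -0.07 (camera, adjusted p = 0.9767), against a range of 1.513e-10 to 0.9767 over the 19 alternatives to this list's test. Within inflammatory (iCAF-like) fibroblasts, tested on their own, Gli1 had a log2 fold change of -6.04 (SE 0.68), Ptch1 of -1.93 (SE 0.83) and Bmp4 of -2.33 (SE 0.52), while Foxf1 stood at 1.78 (SE 0.42). Of the 500 iCAF-like cells of IPI-926 replicate 3, 40 lie outside its cluster. Without the others Gli1 was at -7.18 (SE 1.08), Ptch1 at -1.69 (SE 0.80), Bmp4 at -1.44 (SE 0.58) and Foxf1 at 1.74 (SE 0.44). This Gli1 value is near the floor, since all fibroblasts of IPI-926 replicates 1 and 2 held 2 Gli1 UMIs each. Its size and SE are therefore not well measured.

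**Figure D1:**
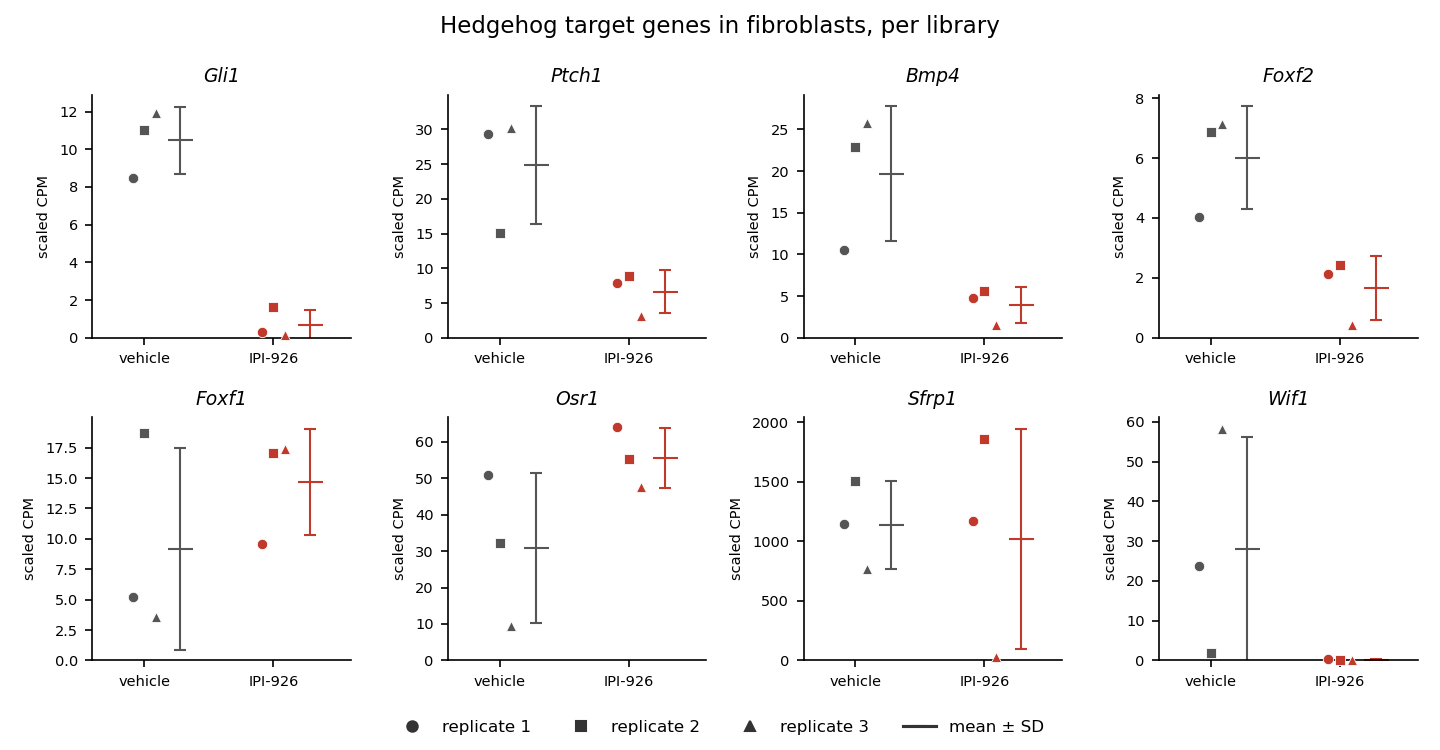
Scaled CPM (CPM after TMM scaling) of 8 Hedgehog target genes in fibroblasts, with a point for each library, the mean as a line and the SD as an error bar for vehicle and IPI-926 (n = 3 each, error bars that would pass below 0 end at the axis). Gli1 lies between 8.46 and 11.9 in the vehicle libraries and between 0.169 and 1.62 in the IPI-926 libraries, while Foxf1 and Osr1 overlap between the groups.

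Mesothelial cells, which line the peritoneal surface of the pancreas, also had lower Hedgehog targets. Gli1 was 6.80 ± 1.33 CPM (unscaled) in vehicle and 0.537 ± 0.751 in IPI-926 mesothelial cells (SD, n = 3 each), a log2 fold change of -3.09 (SE 0.69), and Ptch1 was 21.1 ± 8.36 against 7.00 ± 0.496, a log2 fold change of -1.50 (SE 0.33). These 2 genes fell over the list alone, and both were chosen in this class after their values were seen. The list had a median of -1.12, with 5 of 6 members negative (camera, adjusted p = 4.508e-06), an adjusted p = 0.2897 with an estimated correlation, and an adjusted p = 0.002381 by fry, which asks whether the genes of a list move on balance in 1 direction. Without IPI-926 replicate 2 the log2 fold change of Gli1 was -5.17. The median of the list was -0.51 without vehicle replicate 3, and with equal cells per library its adjusted p = 0.0618 (from 1.483e-07 to 0.2897 over the 18 alternatives). Over all 11591 genes edgeR called 0, with 480 at an unadjusted p under 0.05, DESeq2 32 and limma-voom 0.

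In other classes the Hedgehog readouts were low or similar between the groups. Perivascular Ptch1 was 24.6 ± 11.1 scaled CPM in vehicle (n = 3) and 24.3 ± 6.83 in IPI-926 (n = 2), with Gli1 on 7 UMIs and not tested. Ptch1 had log2 fold changes of -0.34 in endothelial, -0.01 in ductal epithelial and -0.09 in macrophage and monocyte sums, none of them passing. Gli1 had 4 UMIs in endothelial cells, 11 in ductal cells and 7 in macrophages and monocytes. Among named classes the ligands were found mainly in ductal cells, with cells of unnamed clusters left out. In ductal cells Shh was 16.3 ± 7.10 scaled CPM in vehicle and 14.3 ± 17.1 in IPI-926, and Ihh 6.82 ± 2.84 and 8.77 ± 6.37 (SD, n = 3 each, edgeR adjusted p = 0.9999 for both). In IPI-926 replicate 1 these values rest on 7 Shh and 4 Ihh UMIs. The Hedgehog components of fibroblasts, among them Smo, Gli2 and the co-receptor Gas1, had 11 of 14 members negative at a median of -0.17 (camera, adjusted p = 0.4197).

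The fall of Ptch1 was larger in fibroblasts than in each of 4 other classes by value but not past the test. Compared within libraries, the log2 fold change in fibroblasts minus that in perivascular cells was -1.52 (SE 0.53) for Ptch1, and it was -1.65 against endothelial, -1.98 (SE 0.39) against ductal and -1.88 against macrophage and monocyte sums. limma called 0 of 6419, 9816, 11511 and 11076 genes for these 4 comparisons, with 288, 354, 407 and 314 genes at an unadjusted p under 0.05. In simulated data for the endothelial comparison this test recovered 0% of differences at a log2 fold of 1, 5.97% at 2 and 80.3% at 4. Differences of the size seen for Ptch1 would mostly be missed, so the lack of calls does not show equal responses. An edgeR fit with the library as a block called 3 genes against perivascular cells and 0 against each of the others.

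The lists of sugar use and low oxygen were higher in IPI-926 fibroblasts, without a gene passing over all genes. All 13 tested glycolysis genes had positive log2 fold changes with a median of 1.01 (camera, adjusted p = 2.18e-13, and adjusted p = 0.3774 with an estimated correlation), and 9 of them rose over the list alone. The glycolytic enzyme Gapdh went from 753 ± 116 to 1577 ± 478 scaled CPM, Pgk1 from 129 ± 39.9 to 337 ± 180 and Eno1 from 62.0 ± 9.18 to 178 ± 82.3 (SD, n = 3 each). The hypoxia list shares Pgk1, Eno1, Ldha and Aldoa with the first. It had 19 of 21 members positive and a median of 0.73 (adjusted p = 4.93e-10, and adjusted p = 0.3774 with an estimated correlation). Without the cluster of IPI-926 replicate 3 the glycolysis median was 0.61, and the log2 fold change of Gapdh was 0.61 in place of 1.07, that of Pgk1 0.76 in place of 1.38 and that of Eno1 0.91 in place of 1.53.

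Interferon response genes, MHC class I genes and cell division genes were higher in the sums of IPI-926 fibroblasts, with IPI-926 replicate 3 carrying much of the difference. The interferon list had 18 of 19 members positive at a median of 1.63 (camera, adjusted p = 6.243e-12, and adjusted p = 0.6438 with an estimated correlation), which was 0.53 without IPI-926 replicate 3 and 0.50 with equal cells per library. Of MHC class I genes 10 of 10 were positive at a median of 1.22 (adjusted p = 0.001528, and adjusted p = 0.6989 with an estimated correlation), but the median was -0.09 without that library. The G2 and M phase list had 20 of 20 members positive at a median of 1.34 (adjusted p = 1.651e-04, and adjusted p = 0.7038 with an estimated correlation). Its median was -0.57 without IPI-926 replicate 3, -0.50 without the cluster of that library and 2.87 without vehicle replicate 2. Matrix genes such as Col1a1 and Fn1 had a median of 0.25 (adjusted p = 0.3208), which became 0.48 without IPI-926 replicate 3 (adjusted p = 3.61e-05, from 1.468e-06 to 0.9903 over the 19 alternatives).

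The fibroblast genes with the smallest p did not pass over all genes. The imprinted gene Mest was 10.0 ± 5.22 scaled CPM in vehicle and 0.720 ± 0.119 in IPI-926 fibroblasts, a log2 fold change of -3.87 (SE 0.60), and Cnksr2, a scaffold of receptor signalling, had -7.21 (SE 1.40). On the other side the cell adhesion gene Nrcam had 2.95 (SE 0.55), Ndrg4 1.31 (SE 0.25) and the tubulin regulator Stmn4 3.52 (SE 0.78), each with an edgeR adjusted p = 0.8995. Genes of the epithelium were lower in the same fibroblast sums. The classical epithelial list had 10 of 11 members negative at a median of -3.05 (camera, adjusted p = 7.202e-18), ductal markers 16 of 17 at -2.34 (adjusted p = 1.326e-15) and acinar markers 5 of 5 at -5.55 (adjusted p = 3.491e-09), each with an adjusted p = 0.3774 with an estimated correlation. The gastric gene Gkn2 was 29.4 ± 15.2 against 0.310 ± 0.269 scaled CPM.

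WNT target genes did not pass as a list in fibroblasts or endothelial cells. In fibroblasts 7 of 18 members were positive and 11 negative at a median of -0.09 (camera, adjusted p = 0.351), and Axin2, a negative feedback gene and general readout of the pathway, was 18.3 ± 9.74 in vehicle and 24.5 ± 12.1 scaled CPM in IPI-926 libraries (SD, n = 3 each). Lef1, a transcription factor of the pathway, had a log2 fold change of -1.08 (SE 1.39). Without vehicle replicate 2 the fibroblast list had a median of -0.48 and an adjusted p = 0.01417, against 0.01417 to 0.9646 over the 19 alternatives. In endothelial cells 4 of 12 members were positive and 8 negative at a median of -0.15 (adjusted p = 0.8299), with Axin2 at -0.05 (SE 0.40) and Lef1 at -1.19 (SE 1.08).

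Perivascular cells, the pericytes and smooth muscle cells of vessels, had 1 gene that rose and contrary shifts in 2 WNT feedback genes. Plac8, a small cysteine-rich protein of myeloid and tumour cells that also stands in the fixed monocyte list (ENSMUSG00000029322, chromosome 5 from 100553725 to 100572245), rose from 72.3 ± 16.8 to 408 ± 133 scaled CPM (SD, n = 3 and 2 libraries), a log2 fold change of 2.49 (SE 0.31, edgeR adjusted p = 0.02646, higher in 2 of 2 libraries). Over the WNT target list alone Apcdd1, an inhibitor of WNT receptors, rose from 42.0 ± 12.3 to 115 ± 2.82 (log2 fold change 1.44, SE 0.33, adjusted p = 0.0048), and Dkk2, a secreted antagonist, fell from 73.5 ± 45.9 to 5.79 ± 4.07 (-3.53, SE 0.86, adjusted p = 0.0077). Over all 9 tested WNT targets 5 were positive and 4 negative at a median of 0.18 (camera, adjusted p = 0.7907). Mgp, an inhibitor of vessel calcification, was 7068 ± 468 against 2540 ± 97.6 without passing over all genes (-1.48, SE 0.27, adjusted p = 0.2299).

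edgeR tested 6480 perivascular genes, 170 of them at an unadjusted p under 0.05, and DESeq2 called 5 and limma-voom 1. The call of Plac8 was lost without vehicle replicate 1 (adjusted p = 0.1849) or vehicle replicate 3 (0.06764), with the stricter cell filter (0.1477), with doublets kept (0.1135) and with the first doublet score (0.1651). Over all alternatives the adjusted p of Plac8 ranged from 1.91e-11 to 0.1849. IPI-926 replicate 3 had 18 perivascular cells, too few to enter in the main setting. This library did enter with doublets kept (0.20% of its cells) and with the first doublet score (0.28%), where the call was lost in both. In the main setting, leaving out either of the 2 other IPI-926 libraries leaves 1 in that group, under the 2 that a test requires here. Inflammatory NF-kB targets such as Icam1 and Nfkbia had 12 of 13 members positive at a median of 0.72 (camera, adjusted p = 1.273e-07, and adjusted p = 0.4987 with an estimated correlation). This median was 1.13 without vehicle replicate 1, 0.33 without vehicle replicate 3 and 0.08 with doublets kept (adjusted p = 0.4008, from 3.472e-17 to 0.8355 over the 16 alternatives). Interferon genes had 5 of 6 members positive at a median of 0.99 (adjusted p = 3.845e-04, and adjusted p = 0.4987 with an estimated correlation), from 2.434e-08 to 0.6411 over the 16 alternatives. Classical epithelial genes were negative in 6 of 6 at a median of -2.52, or -2.31 with genes absent from a group at their bound (adjusted p = 2.444e-11, and adjusted p = 0.4987 with an estimated correlation). That median was -1.29 without vehicle replicate 3.

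Endothelial cells had slightly lower genes of sprouting and of the VEGF system, and higher genes of DNA replication. All 12 tested VEGF ligands and receptors were negative at a median of -0.32 (camera, adjusted p = 0.003635, and adjusted p = 0.2787 with an estimated correlation), with the main VEGF receptor Kdr at 657 ± 72.9 in vehicle and 588 ± 55.9 scaled CPM in IPI-926 libraries and Vegfa at 13.9 ± 2.74 and 7.76 ± 2.15 (SD, n = 3 each, neither passing over the list alone). Of the tip cell genes, which mark sprouting endothelium, 20 of 22 were negative at a median of -0.25 (adjusted p = 0.004586, and adjusted p = 0.5004 with an estimated correlation), with Esm1 at 247 ± 95.4 and 221 ± 59.6. Early response genes of VEGF had 12 of 15 members negative at a median of -0.21 and did not pass (adjusted p = 0.05838). All 19 tested S phase genes were positive at a median of 0.74 (adjusted p = 2.323e-14, and adjusted p = 0.4518 with an estimated correlation). Tyms, which makes thymidylate for DNA synthesis, rose from 60.3 ± 6.62 to 109 ± 9.77 and the histone chaperone Chaf1b from 5.98 ± 1.23 to 14.0 ± 2.06, both over the list alone.

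Single libraries moved several of these endothelial lists. The tip cell call was lost without vehicle replicate 2 (median -0.05, adjusted p = 0.6974, from 1.36e-07 to 0.6974 over the 18 alternatives) and with equal cells per library. The VEGF response list passed without IPI-926 replicate 1 (-0.34, adjusted p = 0.0266) and without IPI-926 replicate 2 (-0.27, adjusted p = 0.0369), in a range of 0.005179 to 0.5909 over its 18 alternatives, and the VEGF ligands and receptors stood at -0.20 without vehicle replicate 3. The S phase median was 1.39 without vehicle replicate 2 and 0.38 without vehicle replicate 3. G2 and M phase genes were positive in 19 of 19 at 0.66 (camera, adjusted p = 1.008e-06, and adjusted p = 0.5004 with an estimated correlation), but at 0.37 without vehicle replicate 1, 1.85 without vehicle replicate 2, 0.16 without vehicle replicate 3 (call lost) and 0.20 without IPI-926 replicate 1.

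Among single endothelial genes, the capillary transcription factor Meox2 (ENSMUSG00000036144, chromosome 12 from 37108540 to 37179534) rose over the capillary list alone, from 8.05 ± 2.46 to 32.9 ± 6.76 scaled CPM (log2 fold change 2.05, SE 0.29, adjusted p = 7.098e-04, and 0.3629 over all genes). The capillary list as a whole had 4 of 10 members positive at a median of -0.08 (camera, adjusted p = 0.3593). Complement gene Cfb had a log2 fold change of 1.44 (SE 0.32) and did not pass. Of 10227 genes edgeR called 0, with 396 at an unadjusted p under 0.05, DESeq2 14 and limma-voom 0. The tip-like and venous-like sums of the IPI-926 group rest on few cells of its replicates 1 and 2. These held 135 and 71 endothelial cells, 31.1% and 29.6% of them tip-like and 25.2% and 31.0% venous-like. Within these subclasses the protease gene Klk8 rose in tip-like cells from 11.8 to 68.0 scaled CPM (n = 3 and 2 libraries, log2 fold change 2.78, SE 0.41, adjusted p = 0.004831), and Nt5e, the ecto-enzyme CD73, in venous-like cells from 16.9 to 84.8 (n = 3 and 2, log2 fold change 2.27, SE 0.38, adjusted p = 0.03912). DESeq2 called neither (adjusted p = 0.1411 for Klk8, in a range of 3.631e-07 to 0.1411). The call of Nt5e was also lost with limma-voom (adjusted p = 0.09061) and without vehicle replicate 1 or 3 (adjusted p = 0.07047 and 0.3489, from 8.697e-05 to 0.7068 over its alternatives). MHC class II genes were positive in 5 of 5 at a median of 3.50 (adjusted p = 0.003635, and adjusted p = 0.5004 with an estimated correlation), but 0.12 without IPI-926 replicate 3. Classical epithelial genes were negative in 9 of 12 at -2.23 (adjusted p = 1.081e-24, and adjusted p = 0.2174 with an estimated correlation) and ductal markers in 14 of 15 at -2.14 (adjusted p = 1.029e-35, and adjusted p = 0.1736 with an estimated correlation).

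Ductal epithelial cells, which include the tumour cells, had no gene past the test. The mucin Muc20 was 5.69 ± 0.882 in vehicle and 26.4 ± 6.82 scaled CPM in IPI-926 libraries (log2 fold change 2.21, SE 0.27), and Nrn1, a small neuronal growth protein, 6.77 ± 2.73 and 0.193 ± 0.162 (-5.76, SE 0.69), each with an edgeR adjusted p = 0.6324. The neuropeptide Npy had -3.47 (SE 0.54) and xanthine dehydrogenase Xdh 1.93 (SE 0.30). Of 14357 genes tested 423 had an unadjusted p under 0.05, DESeq2 called 18 and limma-voom 0. Classical epithelial genes were negative in 14 of 19 at a median of -0.28 (camera, adjusted p = 1.974e-04), with Gkn1 at -3.51 and Gkn2 at -5.03, neither past the test over the list alone. That median was -0.01 without IPI-926 replicate 1 (call lost), -0.10 without vehicle replicate 1, -0.55 without IPI-926 replicate 2 and -0.66 without IPI-926 replicate 3. Vegfa was 94.7 ± 61.3 against 100.8 ± 28.8.

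Interferon genes were positive in 19 of 19 in ductal cells at a median of 2.504 (camera, adjusted p = 4.367e-12), MHC class I genes in 10 of 10 at 1.71 (adjusted p = 3.065e-04), MHC class II genes in 7 of 7 at 2.80 (adjusted p = 2.343e-04) and G2 and M phase genes in 20 of 20 at 0.69 (adjusted p = 7.801e-06). Macrophage markers moved with them, positive in 16 of 20 at 1.16 (adjusted p = 2.343e-04). With an estimated correlation each of these lists, and the classical epithelial list, had an adjusted p = 0.644. Without IPI-926 replicate 3 the medians were 0.23, -0.48, -0.09, 0.04 and 0.09 and no call was left, and without vehicle replicate 2 that of the macrophage markers was 1.90. The G2 and M phase median also turned to -0.24 with the first doublet score.

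Macrophages and monocytes had higher interferon genes in IPI-926 tumours. Their cell division genes were lower in the main setting but not with the first doublet score. Apoe, the lipid carrier of tissue macrophages (ENSMUSG00000002985, chromosome 7 from 19696109 to 19699188), went from 6697 ± 1099 to 13350 ± 798 scaled CPM (SD, n = 3 each), a log2 fold change of 0.995 (SE 0.21), and rose over the lipid macrophage list alone (adjusted p = 0.0312, and 0.9997 over all genes), which did not pass as a list (camera, adjusted p = 0.2639). The lysosomal protease Ctsk had 1.01 (SE 0.19) and the niacin receptor Hcar2 1.19 (SE 0.23), without passing. Interferon genes were positive in 19 of 19 at a median of 2.44 (camera, adjusted p = 4.181e-20) and MHC class I genes in 11 of 11 at 1.14 (adjusted p = 1.963e-06), which became 0.58 and 0.10 without IPI-926 replicate 3, the second no longer passing. G2 and M phase genes were negative in 20 of 20 at -0.68 (adjusted p = 8.356e-10) and S phase genes in 19 of 20 at -0.44 (adjusted p = 2.161e-06). Genes of cholesterol synthesis such as Idi1 were negative in 17 of 18 at -0.43 (adjusted p = 2.807e-05), and genes induced by dissociation stress, among them Hspa1a and Jun, positive in 19 of 20 at 0.35 (adjusted p = 5.772e-05).

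With an estimated correlation each of these macrophage lists had an adjusted p = 0.6561. The G2 and M phase median was -0.21 without vehicle replicate 1 (call lost), -1.10 without IPI-926 replicate 1 and -0.43 without IPI-926 replicate 2. With the first doublet score it was 1.27, and the list passed in that other direction. For S phase the median was -0.84 without IPI-926 replicate 1, -0.22 without IPI-926 replicate 2 (call lost) and 0.12 with the first doublet score. Cholesterol genes stood at -0.20 without vehicle replicate 2 (call lost) and at -0.23 without IPI-926 replicate 3, and the stress genes at 0.19 without IPI-926 replicate 3. Classical epithelial genes were negative in 15 of 15 at -1.62 (adjusted p = 1.167e-21), or -2.74 without IPI-926 replicate 2, and ductal markers in 20 of 20 at -1.10 (adjusted p = 5.673e-17). Of 13168 genes edgeR called 0, with 249 at an unadjusted p under 0.05, DESeq2 11 and limma-voom 0.

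In lymphocytes 1 epithelial gene passed over all genes tested. Gkn2, a secreted protein of gastric-type epithelium (ENSMUSG00000030049, chromosome 6 from 87373357 to 87379497), had 43 UMIs in vehicle B cells and 0 in IPI-926 B cells, at least 94.4-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 3.152e-05). IPI-926 replicate 1 held 2374562 of the 2982350 UMIs of that group, and without it the bound for Gkn2 is 19.24-fold. In T cells it fell from 93.3 ± 27.1 to 2.11 ± 2.13 scaled CPM, a log2 fold change of -5.64 (SE 0.68, adjusted p = 0.005566), a call lost without vehicle replicate 1 (adjusted p = 0.05418) or 3 (0.1551), in a range of 1.582e-13 to 0.1842 over its alternatives. Neither call was made by limma-voom or with equal cells per library, nor that in B cells with means of per-cell CPM. B cells had 2762 genes tested and 54 at an unadjusted p under 0.05, and T cells 6899 and 111. Summing all cells of a library, edgeR called 0 of 17841 genes, with 697 at an unadjusted p under 0.05, DESeq2 145 and limma-voom 0. Dendritic cells and neutrophils had 0 called of 7336 and 8619 genes, with 225 and 406 at an unadjusted p under 0.05, 7 and 4 by DESeq2 and 0 in both by limma-voom.

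Endothelial, perivascular and acinar cells made up smaller shares of the IPI-926 libraries, with the groups apart in each case in the main setting. Endothelial cells were 5.26 ± 2.81% of vehicle and 1.66 ± 0.45% of IPI-926 cells, perivascular cells 0.913 ± 0.478% and 0.298 ± 0.148%, and acinar cells 0.848 ± 1.30% and 0.0114% (SD, n = 3 each, two-sided exact permutation p = 0.1 each and adjusted p = 0.4). Ductal cells were 27.9 ± 20.8% and 13.2 ± 18.2% (exact p = 0.4), fibroblasts 8.48% and 6.20% (exact p = 0.6), macrophages and monocytes 22.9% and 25.1% (exact p = 0.9), T cells 1.94% and 7.53% (exact p = 0.2) and neutrophils 15.4% and 19.9% (exact p = 0.8). The fibroblast difference of -2.28 percentage points turned to 8.32 with the stricter cell filter, 7.09 with doublets kept, 2.94 at Leiden resolution 2, 3.36 with the first doublet score and 12.62 among non-immune cells. The fibroblast share of IPI-926 replicate 3 rose from 13.7% in the main setting to 39.3% with the stricter filter and 41.9% with doublets kept. It was 29.4% at resolution 2 and 23.6% with the first score. Of the 179 acinar cells 162 were in vehicle replicate 3, and the acinar difference without this library was -0.09 percentage points in place of -0.84, the endothelial -2.02 in place of -3.60 and the perivascular -0.39 in place of -0.61. Since the exact test has no smaller p with 3 libraries against 3, no share could pass it. Among non-immune cells alone the endothelial share was 0.63 percentage points higher and the perivascular share 0.29 points higher in IPI-926 libraries. The perivascular groups lay close, with 0.408% in vehicle replicate 2 and 0.388% in IPI-926 replicate 2. They overlapped without ductal cells in the denominator (0.430% and 0.589% in these libraries) and with the stricter cell filter (0.498% and 0.597%). Both earlier doublet scores also gave overlapping perivascular groups.

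**Figure D2:**
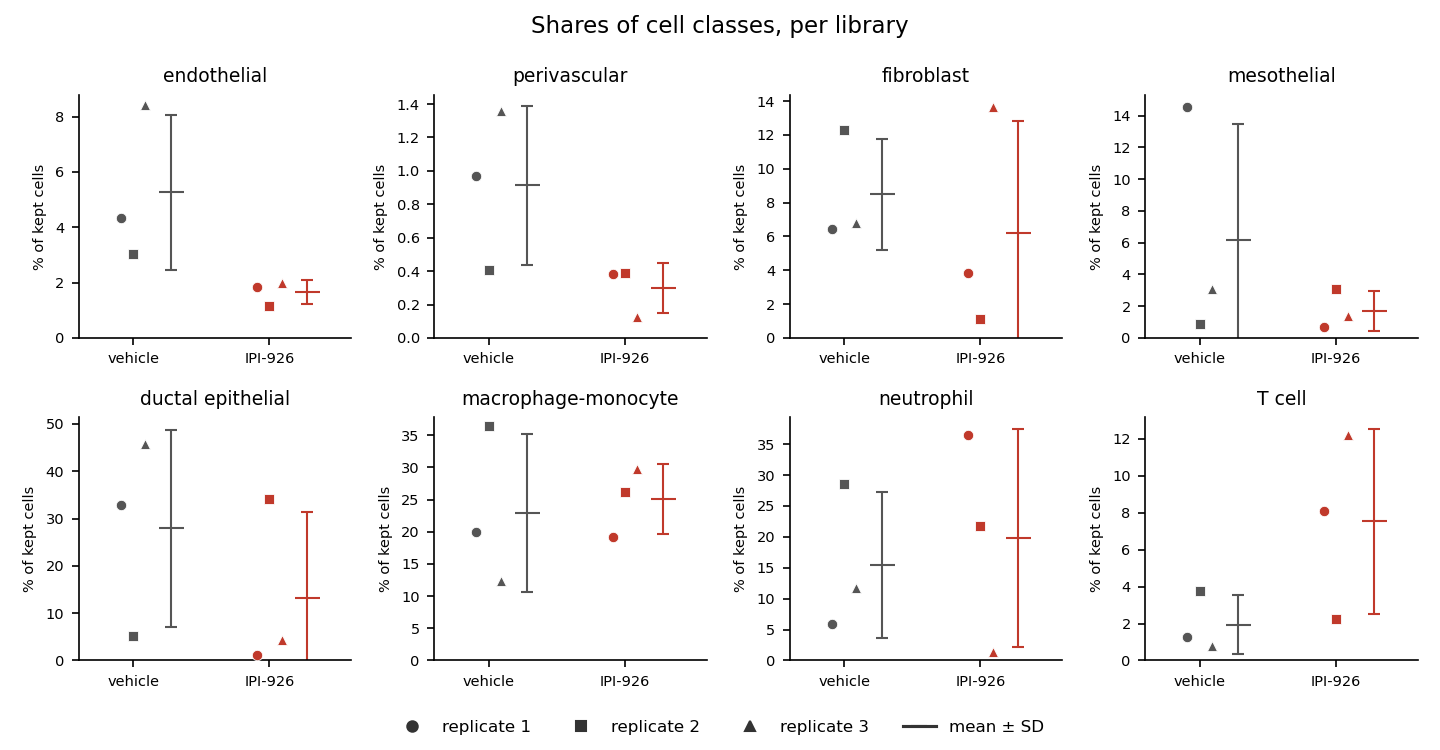
Percent of kept cells that each of 8 cell classes takes in every library, with the mean as a line and the SD as an error bar for vehicle and IPI-926 (n = 3 each, error bars that would pass below 0 end at the axis). Endothelial cells take 5.26% of vehicle and 1.66% of IPI-926 cells on average and perivascular cells 0.913% and 0.298%, while the ductal, fibroblast, macrophage and neutrophil shares overlap between the groups.

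Within fibroblasts, iCAF-like cells took 41.6% in vehicle and 34.3% in IPI-926 libraries (exact permutation p = 0.9). This difference of -7.26 points turned to 10.49 with sub-clustering on all genes, 13.25 at resolution 1, 11.28 without the cluster of IPI-926 replicate 3 and 8.50 without vehicle replicate 3. Contractile, matrix-making myCAF-like cells took 20.3% and 27.0% (exact p = 0.8). Within endothelial cells, tip-like cells took 22.7% and 22% (exact p = 0.9), arterial-like cells 27.8% and 7.14% (exact p = 0.3, a difference of -20.65 points, -31.85 without vehicle replicate 2 and -9.89 without vehicle replicate 3) and venous-like cells 23.2% and 20.3% (exact p = 0.9). In IPI-926 replicate 3, 84.8% of endothelial cells and 70.7% of fibroblasts took no subclass name, which lowers its named shares. In vehicle libraries 12.4% to 32.8% of endothelial cells and 60.0%, 28.9% and 25.4% of fibroblasts took none, so that the named fibroblast shares of vehicle replicate 1 are lowered too.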

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

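The tests of the Hedgehog pattern without the cluster of IPI-926 replicate 3, those within all iCAF-like cells and of Gli1 alone, and those of interferon genes outside macrophages were chosen only after the result was seen. The others were chosen once their pattern had been seen but before the value they measure.

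Differences between the treatment groups that were unequal in fibroblasts and another class within the same libraries are given here as medians of a list's log2 fold change in fibroblasts minus that in the other class. Each passed camera on these differences at its preset correlation, and none passed with an estimated correlation. Several lean on IPI-926 replicate 3, which the perivascular comparison lacks: without it the fibroblast median was -0.57 in place of 1.34 for G2 and M phase and 0.53 in place of 1.63 for interferon response, and the endothelial median of MHC class II was 0.12 in place of 3.50. Against perivascular cells the median difference was -0.47 for tip cell genes, -0.88 for G2 and M phase, 0.51 for hypoxia, 0.52 for glycolysis, -0.56 for NF-kB targets and -1.70 for classical epithelial genes. Against endothelial cells it was -0.89 for venous and adhesion genes, -2.23 for antigen-presenting (apCAF) genes, 0.79 for hypoxia, 0.51 for glycolysis, 0.48 for interferon response, -2.58 for MHC class II, -0.38 for dissociation stress, 0.40 for epithelial-mesenchymal transition, -0.39 for classical epithelial genes, -0.32 for cholesterol synthesis and -0.28 for mitochondrially encoded genes. Against ductal cells it was -1.28 for apCAF genes, 0.48 for glycolysis, -1.77 for MHC class II, 0.28 for oxidative phosphorylation and 0.45 for ribosomal proteins. Against macrophages and monocytes it was -0.69 for Notch response, 1.17 for S phase, 1.73 for G2 and M phase, 0.80 for hypoxia, 0.87 for glycolysis, -0.98 for dissociation stress, -0.57 for classical epithelial genes and 0.32 for ribosomal proteins. The apCAF and MHC class II lists share H2-Aa, H2-Ab1, H2-Eb1 and Cd74, and the hypoxia and glycolysis lists share Pgk1, Eno1, Ldha and Aldoa. The differences of lists that share genes are not independent of each other.

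The lower Hedgehog targets of IPI-926 fibroblasts were weighed against 3 technical sources. UMIs of other cells diluting the fibroblast sums would lower fibroblast markers too. The 20 tested ones had a median log2 fold change of 0.33 (SD 0.62), which argues against this source, but weakly. The same markers named the class, Sfrp1 is on both lists, and the sums include the cluster of IPI-926 replicate 3. Cells found in 1 library alone are argued against for Gli1 and Ptch1, whose median was -3.07 without that cluster. This source stays open for Bmp4 at -1.55 and for the list at -0.61. Foxf2 was 0.33 (SE 0.95) without the cluster, as this source predicts. However, IPI-926 replicates 1 and 2 also stood low, at 2.05 and 2.43 CPM (unscaled, on 14 and 3 UMIs). The vehicle libraries stood at 4.12, 6.745 and 7.435, so the source stays open for Foxf2 too. Another mix of fibroblast subclasses was tested within the iCAF-like cells outside that cluster, where Gli1 stood at -7.18, past the bound of its test. All fibroblasts of IPI-926 replicates 1 and 2 held 2 Gli1 UMIs each, so this fold is near the floor and its size is not measured. Its direction argues against this source for Gli1, without excluding it. Within all iCAF-like cells Gli1, Ptch1 and Bmp4 had a median of -2.33, each past the bound of its test, but all but 40 of the 500 such cells of IPI-926 replicate 3 are of that cluster. Outside it the median was -1.69, with Ptch1 and Bmp4 too near the bound for their error, so this source stays open for these 2. It also stays open for the list at -0.70, since its members went both ways. Whether the cells of that cluster are fibroblasts or mesenchymal tumour cells stays open, and every IPI-926 fibroblast value that includes them depends on it.

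Epithelial genes, led by Gkn1, Gkn2 and Tff1, were lower in non-epithelial classes of the IPI-926 libraries. Free epithelial RNA could account for this: over 25 epithelial genes the log2 fold changes in macrophages and in neutrophils followed each other with Pearson r = 0.977 (0.927 to 0.991 over resampled genes, which are not independent replicates). Doublets with epithelial cells are argued against, since the 5% of vehicle macrophages with the most classical epithelial UMIs held at most 21.9% of them (10.6%, 19.5% and 21.9% by library), and 100%, 78.9% and 98.3% of all vehicle macrophages had such a UMI against 26.7%, 93.6% and 43.3% after IPI-926. Lower expression by the ductal cells themselves stays open, as does their lower share in IPI-926 replicate 3. The low share in IPI-926 replicate 1 depends on naming, with 84 ductal cells, or 848 with unnamed clusters joined.

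Interferon response genes were higher in several classes of the IPI-926 libraries. IPI-926 replicate 3 alone could account for most of this in 3 classes, as the median log2 fold change of the list was 2.44 with it and 0.58 without it in macrophages, 1.63 and 0.53 in fibroblasts and 2.504 and 0.23 in ductal cells. It is argued against in neutrophils, at 1.34 with it and 1.22 without it, and in perivascular cells, which had 0.99 without any sum of that library. The rest stays open between a response to the drug and differences between mice.

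The 6 libraries split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05, so that only the real value and the highest of the other splits are given. Called genes were 0 in the real split and at most 0 in the others in fibroblasts, endothelial cells and ductal cells, where all 10 splits did as well, 0 and 1 in macrophages and monocytes, 0 and 2 for all cells summed and 0 and 1 for the differences between classes, again with all 10 splits at or above the real one. For the lists the measure was the negative decimal logarithm of the camera p. It was 8.395 against 2.65 for Hedgehog targets in fibroblasts (1 split as high, the real one, which is counted here and below), 0.657 against 4.371 for WNT targets in fibroblasts (6 splits), 0.107 against 1.828 for WNT targets in endothelial cells (8 splits), 1.632 against 2.505 for VEGF response (2 splits) and 2.846 against 6.126 for tip cell genes (4 splits).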

How the results depend on the processing

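The earlier doublet scores, fibroblasts and iCAF-like cells without the cluster of IPI-926 replicate 3 and unnamed clusters joined were run only after the results were seen, and every other alternative was planned. Of 833 values of gene lists under an alternative, 711 kept their direction and side of the threshold, 103 no longer passed, 6 newly passed and 13 changed direction. Of 1401 values of named genes, 1290 kept both, 18 no longer passed, 28 newly passed and 65 changed sign. Shares kept their direction in 161 of 186 values, with the side of the threshold checked too only for edgeR on cell counts. Counts of called genes stayed within 1.5 times in 194 of 269 values. Those of the differences between classes did so in 25 of 27, and those of Hedgehog targets over the list alone in 20 of 22. Counts of called genes in the main setting were 0 or 1 in each class and 0 for each difference between classes. A count kept can thus be a 0 that stayed 0, which shows no robustness. The tallies also include fits that leave 1 library in a group. In fibroblasts Gli1 ran from -5.65 to -2.81 over 20 alternatives and Ptch1 from -2.58 to -1.28 over 22. Depth and the lack of 1 library may both limit perivascular tests, with 24 cells in IPI-926 replicate 2: at a biological coefficient of variation of 0.269, 52.2% of genes changed by a log2 fold of 2 were recovered in simulated data, against 91% in endothelial cells at 0.2701. In deeper sums the spread between libraries goes with lower recovery, 22.4% in fibroblasts at 0.4697 and 2.99% for all cells summed at 0.5481. Equal cells per library leaves fewer genes to test, 4 of 8 Hedgehog targets among them, and leaving out a library leaves fewer samples. In perivascular, tip-like and venous-like cells leaving out an IPI-926 library leaves 1 in its group, under the 2 that a test requires, so those values test nothing. For the changes given next the cause was not tested otherwise. No paired analysis was possible because the labels carry no replicate numbers that pair mice of the 2 groups.

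With DESeq2, called genes numbered 2 in B cells, 5 in T cells, 7 in dendritic cells, 18 in ductal cells, 14 in endothelial cells, 36 in fibroblasts, 11 in macrophages, 32 in mesothelial cells, 4 in neutrophils, 5 in perivascular cells, 145 in all cells summed, 22 in iCAF-like fibroblasts, 0 in tip-like endothelial cells and 0 in venous-like endothelial cells, and the log2 fold change was 0.0084 for Ptch1 in perivascular cells. With Leiden resolution 0.5, log2 fold changes were 0.012 for Shh in ductal cells and 0.016 for Ptch1 in ductal cells. With Leiden resolution 2, called genes numbered 3 in mesothelial cells, and log2 fold changes were 0.0074 for Ptch1 in perivascular cells and 0.0022 for Ptch1 in ductal cells, and the share differed by 2.94 for fibroblasts. With RLE size factors, called genes numbered 2 in B cells, and the log2 fold change was 0.0016 for Ptch1 in ductal cells. With a threshold of 0.1, called genes numbered 3 in B cells, 1 in dendritic cells, 1 in neutrophils and 3 in venous-like endothelial cells. With camera with an estimated correlation, the adjusted p was 0.377 for Hedgehog targets in fibroblasts and 0.5004 for tip cell genes in endothelial cells. With non-immune cells as the denominator, the share differed by 12.62 for fibroblasts, 0.29 for perivascular cells and 0.63 for endothelial cells. With a denominator without ductal cells, the share differed by -0.22 for macrophages. With doublets kept, log2 fold changes were 0.18 for Ptch1 in perivascular cells and 0.10 for Kdr in ductal cells, and the share differed by 7.09 for fibroblasts. With the edgeR interaction, called genes numbered 3 for the difference between fibroblasts and perivascular cells. With edgeR on cell counts, the adjusted p was 0.0153 for acinar cells. With equal cells per library, called genes numbered 1 in neutrophils, 2 in perivascular cells and 0 for Hedgehog targets lower over the list alone, and the adjusted p was 0.977 for Hedgehog targets in fibroblasts, 0.00518 for VEGF response in endothelial cells and 0.481 for tip cell genes in endothelial cells, and log2 fold changes were 0.33 for Ptch1 in ductal cells and 0.025 for Ptch1 in macrophages. With the first doublet score, called genes numbered 0 in perivascular cells, and the adjusted p was 0.748 for S phase in macrophages and 5.03e-11 for G2 and M phase in macrophages, and log2 fold changes were -0.12 for Foxf1 in perivascular cells, 0.085 for Axin2 in endothelial cells and 0.039 for Kdr in ductal cells, and the share differed by 3.36 for fibroblasts. With fry, the adjusted p was 0.521 for Hedgehog targets in fibroblasts and 0.591 for tip cell genes in endothelial cells. With limma-voom, called genes numbered 3 in B cells, 0 in T cells, 2 in tip-like endothelial cells and 0 in venous-like endothelial cells, and log2 fold changes were 1.84 for Esm1 in fibroblasts, 0.036 for Ptch1 in perivascular cells, 0.076 for Axin2 in endothelial cells and 0.23 for Shh in ductal cells. With a mean of at least 10 CPM, called genes numbered 4 in B cells, 3 in tip-like endothelial cells, 2 in venous-like endothelial cells and 3 for Hedgehog targets lower over the list alone, and the log2 fold change was 0.020 for Ptch1 in ductal cells. With means of per-cell CPM, called genes numbered 0 in B cells, 1 in macrophages, 1 in neutrophils and 4 in perivascular cells, and log2 fold changes were 0.025 for Axin2 in endothelial cells, -0.21 for Ihh in ductal cells, 0.11 for Ptch1 in ductal cells and -0.088 for Kdr in macrophages. With no expression filter, called genes numbered 22 in B cells, 20 in T cells, 18 in dendritic cells, 4 in endothelial cells, 1 in mesothelial cells, 31 in neutrophils, 19 in perivascular cells, 32 in tip-like endothelial cells and 37 in venous-like endothelial cells, and the adjusted p was 0.785 for WNT targets in endothelial cells. With the second doublet score, called genes numbered 2 in B cells, and the adjusted p was 0.956 for WNT targets in endothelial cells, and log2 fold changes were -0.075 for Axin2 in fibroblasts, 0.061 for Ptch1 in ductal cells and 0.15 for Kdr in ductal cells. With the stricter cell filter, called genes numbered 2 in B cells, 1 in neutrophils and 0 in perivascular cells, and log2 fold changes were 0.050 for Axin2 in endothelial cells, 0.049 for Shh in ductal cells and 0.057 for Ptch1 in ductal cells, and the share differed by 8.32 for fibroblasts. With sub-clustering at resolution 1, the share differed by 13.25 for iCAF-like cells. With sub-clustering with all genes, the share differed by 10.49 for iCAF-like cells. With unnamed clusters joined, the log2 fold change was 0.090 for Ptch1 in ductal cells. Without sex-linked genes and markers of other classes, called genes numbered 3 in B cells and 1 in neutrophils. Without the single-library cluster, the adjusted p was 0.535 for Hedgehog components in fibroblasts, and log2 fold changes were 0.33 for Foxf2 in fibroblasts, 0.94 for Sfrp1 in fibroblasts and -0.016 for Vegfa in fibroblasts, and the share differed by 11.28 for iCAF-like cells.

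Leaving out 1 library at a time, called genes numbered 1 to 7 for B cells, 0 to 3 for T cells, 0 to 3 for dendritic cells, 0 to 3 for endothelial cells, 0 to 1 for macrophages, 0 to 2 for mesothelial cells, 0 to 2 for neutrophils, 0 to 6 for perivascular cells, 2 to 33 for tip-like endothelial cells, 0 to 25 for venous-like endothelial cells and 0 to 1 for the difference between fibroblasts and perivascular cells. The adjusted p of lists then ran from 0.0142 to 0.965 for WNT targets in fibroblasts, 0.248 to 0.999 for WNT targets in endothelial cells, 0.0266 to 0.386 for VEGF response in endothelial cells and 1.36e-07 to 0.697 for tip cell genes in endothelial cells, and from 0.119 to 0.947 for Hedgehog components in fibroblasts, 8.4e-06 to 0.827 for MHC I in fibroblasts, 1.48e-11 to 0.537 for G2 and M phase in fibroblasts, 9.18e-10 to 0.167 for MHC I in ductal cells and 6.2e-11 to 0.87 for MHC II in ductal cells. Log2 fold changes ran from -0.93 to 0.43 for Sfrp1 in fibroblasts, -0.28 to 0.49 for Vegfa in fibroblasts, -0.86 to 0.97 for Esm1 in fibroblasts, -0.36 to 0.29 for Ptch1 in perivascular cells, -0.14 to 0.34 for Foxf1 in perivascular cells, -1.19 to 1.10 for Axin2 in perivascular cells and -0.39 to 0.18 for Esm1 in endothelial cells. For other genes they ran from -0.28 to 0.10 for Axin2 in endothelial cells, -1.76 to 0.33 for Shh in ductal cells, -1.17 to 0.059 for Axin2 in ductal cells, -0.18 to 0.12 for Ptch1 in ductal cells, -0.19 to 0.75 for Vegfa in ductal cells, -0.15 to 0.94 for Vegfa in macrophages and -0.31 to 0.17 for Ptch1 in macrophages. Share differences in percentage points ran from -26.11 to -5.79 for ductal cells, -6.01 to 0.25 for fibroblasts, -0.87 to -0.39 for perivascular cells, -4.72 to -2.02 for endothelial cells, -3.14 to 8.89 for macrophages, -3.82 to 13.75 for neutrophils, 3.24 to 8.23 for T cells, -1.24 to -0.089 for acinar cells, -18.91 to 8.50 for iCAF-like cells, -8.18 to 22.90 for myCAF-like cells, -8.73 to 9.73 for tip-like cells, -31.85 to -9.89 for arterial-like cells and -8.30 to 4.89 for venous-like cells.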

Other observations

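Neutrophils of IPI-926 tumours had higher interferon and stress genes and lower genes of mitochondrial respiration. Interferon response genes were positive in 13 of 14 at a median log2 fold change of 1.34 (camera, adjusted p = 3.08e-13, and adjusted p = 0.513 with an estimated correlation), and 8 of them rose over the list alone. That median was 2.13 without IPI-926 replicate 2. Dissociation stress genes were positive in 18 of 20 at 0.64 (adjusted p = 2.302e-08, and adjusted p = 0.4389 with an estimated correlation), and oxidative phosphorylation genes were negative in 20 of 20 at -0.46 (adjusted p = 7.959e-06, and adjusted p = 0.513 with an estimated correlation). Classical epithelial genes were negative in 12 of 12 at -1.37 (adjusted p = 1.161e-10, and adjusted p = 0.513 with an estimated correlation), with -0.78 without IPI-926 replicate 1 and -4.90 without IPI-926 replicate 2.

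Mesothelial cells had higher glycolysis genes, positive in 13 of 13 at a median of 0.78 (camera, adjusted p = 1.26e-10, and adjusted p = 0.5214 with an estimated correlation), beside their lower Hedgehog targets. Their classical epithelial genes were negative in 11 of 11 at -1.77 (adjusted p = 5.267e-22, and adjusted p = 0.2897 with an estimated correlation), or -3.49 without IPI-926 replicate 2. In T cells the same list was negative in 10 of 10 at -1.20 (adjusted p = 5.603e-16, and adjusted p = 0.4074 with an estimated correlation), or -3.76 without IPI-926 replicate 2.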
